A study of Homo sapiens with 8 samples.

How the data were processed

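The 8 libraries came from HEK293T cells: sorted P-bodies 1 and 2, cytosol 1 and 2, siEDC4 1 and 2 and siNC 1 and 2, grouped by the labels' sample group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from 50 ng of sorted P-body RNA, 100 ng of cytosolic RNA or 500 ng of total RNA with a YEASEN kit. The submitters' processing notes name FastQC 0.11.9, cutadapt 1.18, STAR 2.7.9a, featureCounts 2.0.1 and hg38. The annotation, whether strand was used in counting, how reads with several matches were treated and how edited sites were called are not given in the sources used here. For that reason genes with near-identical copies and genes that overlap are uncertain, and a score of 0 is a listed 0, which a filter on sites can produce.

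The authors deposited raw read counts per gene for the sort, 59414 genes in all, as whole numbers with no normalization per the file headers and values. The authors also deposited, for each editor and each contrast, a table with the edited reads, the reads and the editing score of each gene. The deposited reads columns were entered as estimated counts because the broken lines hold values that are not whole; every reads value used was a whole number. The deposited editing score is a fraction; it equalled edited reads over reads to within 5.0e-08 in every table and is given here as a percentage. The tables list 11969 genes (A-to-I, sort), 11777 (C-to-U, sort), 10643 (A-to-I, knockdown) and 10833 (C-to-U, knockdown), and 3 broken lines of ANK2 per editing table were left out. Depth differs between tables and genes, which sets the precision of a score; intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was given the upper limit of 3 counts, and counting intervals are exact at 95%.

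Abundance was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene types came from the GENCODE v29 annotation of hg38, in which 57167 of the gene identifiers were found. Gene identifiers and coordinates came with the deposited counts, whose annotation is not given. Editing was tested with the same edgeR test on edited and unedited reads, with 1 effect per library for abundance and 1 for the group's edited share, over genes with an edited read in at least 2 libraries. The SE of an edgeR estimate is the size of the estimate over the square root of the test's F statistic, so it restates the test. The plan written before the data were examined had named limma 3.58.1 on log2 scores unless the files gave edited and total reads. They did, so the count test took its place and limma, with a pseudocount of 0.970% (A-to-I) or 0.182% (C-to-U) in the sort and 0.336% or 0.409% in the knockdown, was run as an alternative. Gene lists of at least 5 measured members were tested with camera at a preset correlation of 0.01, on log-CPM or log2 scores. The lists were P-body components, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, proteasome subunits, glycolysis, secretory and endoplasmic reticulum, chromatin modifiers, ubiquitin ligases and deubiquitinases, immediate early and AU-rich element mRNAs, stress response, interferon response, replication-dependent histones, cell cycle and mitosis, nuclear noncoding RNAs, cytoplasmic noncoding RNAs, nuclear export and pore, markers of blood cells, fibroblasts and epithelial tumour lines, and genes named ZNF with a number.

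Lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. For the counts the rule took the 12 largest rises and 12 largest falls among genes that passed, moved the same way in both same-numbered pairs, carried a gene symbol and reached a mean of 10 CPM in a group. It added the 3 members with the smallest p of each list that passed, and DDX6, EDC4, LSM14A, DCP1A, ADARB1 and APOBEC1. For each editing table it took the 8 largest changes each way, or, where fewer than 4 genes passed, the 8 highest scores in the control group, plus EDC4, DDX6, LSM14A and DCP1A. The comparison of reads after the knockdown was added after the data were seen and used the editing tables' rule.

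Replicates were compared by a chi-square test of their reads over genes with at least 10 reads. The siNC libraries gave a chi-square of 1.02 per degree of freedom in both knockdown tables (p = 0.062 and 0.047), the siEDC4 libraries 3.46 and 3.47, the cytosol libraries 3.00 and the sorted P-body libraries 22.5. The siNC libraries' edited reads differed by more than sampling noise (1.30 and 1.31 per degree of freedom). They were counted as 1 sample, with reads summed, in the knockdown's main test. The fit of 4 libraries, planned as the main one, was made an alternative after this was seen, and the replicate block was fitted with 4 libraries too. For medians the mean of both siNC libraries was used as 1 value. The labels give each replicate number a batch tag of its own, shared across groups, so the numbers pair the samples. Deviations of same-numbered samples from their group means correlated at 0.036 in the counts, -0.026 and 0.0037 in the sort's A-to-I and C-to-U scores, -0.034 in the knockdown's reads and 0.026 and 0.027 in its scores.

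Each model was tested on simulated data with known changed genes, at most 67 tested per size of change. The counts test recovered 38.8% of genes changed 1.5-fold, 79.7% at 2-fold and 98.5% at 4-fold over 18358 genes, with 2.76% false calls. The knockdown reads test recovered 67.2%, 89.6% and 100% over 10641 genes, with 6.04% false calls. The sort's A-to-I test recovered 26.9%, 48.5% and 75.8% over 11186 genes and its C-to-U test 0%, 20.0% and 39.4% over 10316. Far more genes passed in the sort itself (10841 of 18745 for abundance). The adjustment is stricter where few genes change, so the simulated rates do not carry over to the sort's tests. The knockdown's editing tests recovered 0% at every size. The alternatives were other scalings, filters, pseudocounts and centring, DESeq2 1.42.0, limma, the replicate block, leaving out each library in turn except those of siEDC4, an estimated correlation for lists and a correction for gene length. With an estimated correlation camera relies on the residual degrees of freedom of very few libraries. It then has little power, so a call lost in that setting decides nothing about a list.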

Results

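HEK293T cells, an established line derived from human embryonic kidney, carried RNA editors directed to processing bodies (P-bodies), the cytoplasmic granules that gather mRNA decay and repression proteins with stored mRNA. One editor changes adenosine to inosine (A-to-I, the TRIBE approach, built on an ADAR deaminase domain). The other changes cytidine to uridine (C-to-U, the STAMP approach, built on an APOBEC deaminase). Edited bases are read here as marks of RNA that met an editor. No library without the editors was included, so editing from other sources and base variants cannot be separated from the editors' marks. The libraries formed 4 groups of 2: sorted P-bodies, cytosol, cells treated with an siRNA against EDC4 (siEDC4) and cells treated with a control siRNA (siNC). EDC4 encodes a scaffold protein of the mRNA decapping machinery. Library input was 50 ng of RNA for sorted P-bodies, 100 ng for cytosol and 500 ng for the knockdown groups, so fraction and input amount went together. Gene counts summed to between 21186963 and 23716926 per library in the sort. In the sort's editing tables, reads of listed genes summed to between 12048147 and 15947999 per library, and in the knockdown's tables to between 5697417 and 6294767. Nothing in the labels says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The siNC libraries differed in reads per gene by close to sampling noise alone (chi-square per degree of freedom 1.02 over 10642 genes, p = 0.062 in the A-to-I table; 1.02 and p = 0.047 in the C-to-U table). Their edited reads differed by more than that (1.30 and 1.31), as did the reads of the siEDC4 libraries (3.46). The siNC libraries were counted as 1 sample, with their reads summed, so the spread behind the knockdown tests came from the siEDC4 libraries alone.

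The sort asked which RNAs are enriched in P-bodies. mRNAs of actin-linked proteins made up 9 of the 12 largest rises in the sorted fraction. SYNE2, a giant nesprin that ties the nucleus to actin, was present at 1928 ± 414 CPM (counts scaled to the TMM library size) in sorted P-bodies and 99.9 ± 5.25 CPM in cytosol (SD, n = 2 each), a log2 fold change of 4.27 ± 0.17 (SE, adjusted p = 7.1e-07, edgeR). UTRN, a relative of dystrophin, rose by 4.03 ± 0.16, the nonmuscle myosin heavy chains MYH10, MYH9 and MYH14 by 3.88 ± 0.13, 3.86 ± 0.13 and 3.70 ± 0.12, and the actin-linked genes MYO6, DBN1, PPP1R9A and GSN by 3.74, 3.69, 3.56 and 3.41 (adjusted p from 5.2e-07 to 7.1e-07, edgeR). Among noncoding RNAs, SNORA73B rose by 3.49 ± 0.13, SNORD3A by 3.38 ± 0.12 and MIR3648-1 by 5.06 ± 0.31. MIR3648-1 was at only 0.588 ± 0.210 CPM in cytosol, and it and SNORD3A have near-identical copies, so both are uncertain. At the other end stood RNY1, a small cytoplasmic Y RNA bound by the Ro protein, at 3.23 ± 0.058 CPM in sorted P-bodies and 129 ± 8.64 CPM in cytosol (log2 fold change -5.32 ± 0.13, adjusted p = 1.7e-07, edgeR).

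SYNE2 (ENSG00000054654.19) lies on chromosome 14 at 63761899 to 64226433 in hg38, UTRN on chromosome 6 at 144285701 to 144853034, MYH10 on chromosome 17 at 8474207 to 8630761, MYH9 on chromosome 22 at 36281280 to 36387967 and RNY1 (ENSG00000201098.1) on chromosome 7 at 148987136 to 148987248. The other large falls were mitochondrial, histone and signal-recognition-particle RNAs: MT-ND4L (-3.55), MT-ND4 (-3.50), MT-ATP8 (-2.76), MT-ATP6 (-2.75), RN7SL4P (-3.12), H2AC20 (-3.0), H2BC21 (-2.98) and H4C4 (-2.89). S100A11, a small calcium-binding protein, changed by -2.90, HMGA1, a chromatin architectural protein, by -2.69, and NPIPB3, a member of a repeated gene family, by -2.84. Adjusted p for these lay between 6.1e-07 and 7.8e-06 (edgeR). MT genes, RN7SL4P, histones and NPIPB3 have near-identical copies elsewhere in the genome, so their counts are uncertain.

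**Figure D1:**
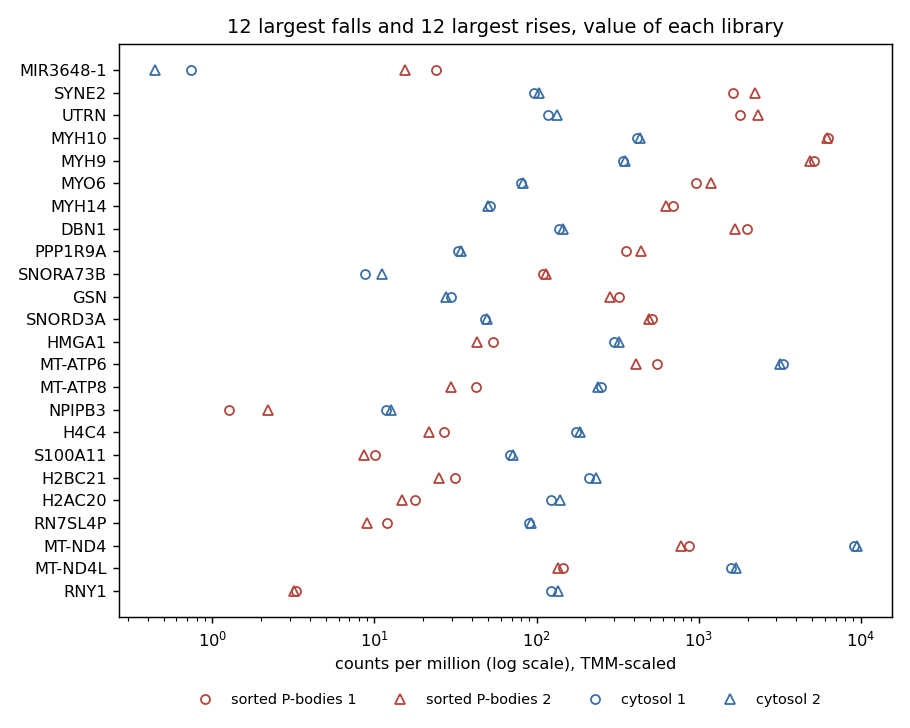
CPM (TMM-scaled, log scale) in each library for the 12 genes with the largest rise and the 12 with the largest fall in sorted P-bodies. Sorted libraries are red and cytosol libraries blue, and genes were picked to move the same way in both pairs; SYNE2 stood at 1635 and 2220 against 96.2 and 104 CPM.

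Of 18745 genes tested, 5401 were higher and 5440 lower in sorted P-bodies at an adjusted p under 0.05 (edgeR), and 2753 and 1835 of them differed by more than 2-fold. Protein-coding genes took 94.7% of the reads in sorted P-bodies and 88.7% in cytosol, with 4471 higher and 4535 lower. Mitochondrial chromosome genes took 1.37% of reads in sorted P-bodies and 6.49% in cytosol, and 16 of 28 were lower. snoRNAs took 0.088% against 0.028%, with 26 of 114 higher and 9 lower, and most of their share in sorted P-bodies came from SNORD3A (507 CPM) and SNORA73B (112 CPM). With library size as the only scaling, the median log2 fold change of all genes moved from -0.03 to -0.23, and 4257 genes were higher and 6911 lower.

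Of the fixed lists, 5 passed downwards. Of the cytosolic ribosomal protein genes, 75 of 78 were lower and 0 higher, with a median log2 fold change of -1.37 (camera adjusted p = 1.0e-17), as for RPS13 (-2.16), RPL12 (-2.14) and RPL32 (-2.01). Of the nuclear-encoded oxidative phosphorylation genes, 64 of 77 were lower and 4 higher (median -1.003, camera adjusted p = 4.1e-11), as for COX6B1 (-2.17), UQCR10 (-1.90) and NDUFB11 (-1.88). The mitochondrially encoded mRNAs had 12 of 13 lower (median -2.23, camera adjusted p = 1.9e-05). Secretory and endoplasmic reticulum genes had 22 of 32 lower and 4 higher (median -0.81, camera adjusted p = 0.00028), as for DAD1 (-1.87), the retrieval receptor KDELR1 (-1.74) and the translocon subunit SEC61B (-1.70). Replication-dependent histones, whose mRNAs carry no poly(A) tail, had 31 of 37 lower and 0 higher (median -1.87, camera adjusted p = 4.1e-11), as for H2AC6 (-2.40). None of these 5 lists passed with an estimated correlation (camera adjusted p = 0.691). That setting has little power with so few libraries, so it cannot decide whether the lists moved.

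Another 4 lists passed upwards. Of the ubiquitin ligases and deubiquitinases, 40 of 47 were higher and 0 lower (median 1.07, camera adjusted p = 6.4e-11), as for BIRC6 (2.48), UBR3 (2.20) and UBR1 (2.18). Zinc finger genes had 281 of 415 higher and 48 lower (median 0.85, camera adjusted p = 4.1e-11), as for ZNF420 (2.89), ZNF823 (2.26) and ZNF443 (2.20). Chromatin modifiers had 38 of 60 higher and 15 lower (median 0.66, camera adjusted p = 0.0060), as for the histone demethylases KDM5A (2.20) and KDM5B (1.75). Cell cycle and mitosis genes had 22 of 40 higher and 10 lower (median 0.37, camera adjusted p = 0.033), as for TTK (2.03), CCNE2 (1.89) and E2F3 (1.51). Adjusted over the list alone, the counts became 1 higher among mitochondrially encoded mRNAs, 32 lower histones, 16 lower chromatin modifiers, 23 higher cell cycle genes, and 284 higher and 51 lower zinc finger genes, and the other called lists kept theirs. These 4 lists too lost their call with an estimated correlation (adjusted p = 0.691, and 0.699 for cell cycle and mitosis). Chromatin modifiers lost it once the trend with gene length was removed (adjusted p = 0.569), and cell cycle and mitosis lost it without sorted P-body library 1 or without cytosol library 1.

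**Figure D2:**
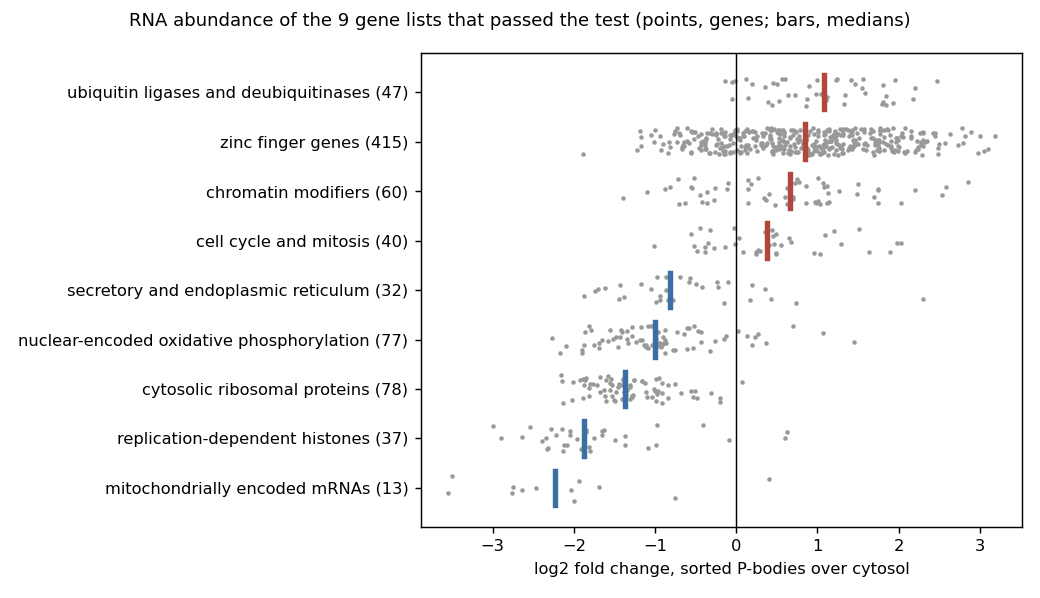
Log2 fold change of RNA abundance, sorted P-bodies over cytosol, for the measured members (points, number in parentheses) and the median (bar) of the 9 gene lists that passed the camera test. Medians run from -2.23 for mitochondrially encoded mRNAs to 1.07 for ubiquitin ligases and deubiquitinases.

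mRNAs for the P-body's own proteins did not move as a group: 12 of 24 P-body components were higher and 6 lower (median 0.28, camera adjusted p = 0.376). DCP1A, a decapping activator, rose by 1.14 ± 0.12 (296 ± 34.8 against 134 ± 7.39 CPM, adjusted p = 4.1e-05, edgeR), the repressor LSM14A by 0.38 ± 0.11 (adjusted p = 0.016) and the helicase DDX6 by 0.34 ± 0.11 (adjusted p = 0.025). EDC4 (0.22 ± 0.10, adjusted p = 0.098) and ADARB1 (-0.20 ± 0.11, adjusted p = 0.139) did not pass. Entries of the count table named for parts of the constructs did not differ: APOBEC stood at 546 ± 22.6 and 504 ± 6.52 CPM (adjusted p = 0.391), MYCT2AGFP at 431 ± 15.5 and 449 ± 11.5 CPM (adjusted p = 0.652) and HAT2AmCherry at 203 ± 10.5 and 206 ± 2.68 CPM (adjusted p = 0.871, all edgeR). Endogenous APOBEC1 and the entries Tad-8e and Tad-X had 0 counts in all libraries, which allows up to 0.142 CPM. With the replicate block DDX6 no longer passed (adjusted p = 0.084, edgeR), and neither DDX6 nor LSM14A passed under library-size scaling (adjusted p = 0.294 and 0.199) or without cytosol library 1 (0.308 and 0.192) or 2 (0.301 and 0.308). ADARB1 passed under library-size scaling (-0.40, adjusted p = 0.012, edgeR). It stood at -0.27 without sorted library 1 and at -0.17 without sorted library 2, and EDC4 at 0.28 without sorted library 2. With 1 library left out, its group adds no spread to the test. The cytosol libraries differed less from each other than the sorted ones, so calls without a sorted library come more easily.

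Other fixed lists did not pass. Translation factors (9 higher and 17 lower of 34), proteasome subunits (8 and 15 of 31) and glycolysis genes (3 and 8 of 17) each had a camera adjusted p of 0.288 and medians of -0.22, -0.32 and -0.29. Immediate early and AU-rich element mRNAs had 10 higher and 6 lower of 29 (camera adjusted p = 0.281) and stress response genes 7 and 5 of 21 (adjusted p = 0.525). Interferon response genes had 7 and 5 of 15 (adjusted p = 0.376) and nuclear export and pore genes 5 and 2 of 12 (adjusted p = 0.525). Nuclear noncoding RNAs had 4 higher and 4 lower of 13 (camera adjusted p = 0.837) and cytoplasmic noncoding RNAs 4 and 9 of 18 (adjusted p = 0.394). Fibroblast markers had 1 higher and 1 lower of 6 (camera adjusted p = 0.962; median -0.14, mean 0.0013). Of 12 blood cell markers 1 was measured and was lower, and 3 of 4 measured epithelial tumour line markers were lower. Adjusted over the list alone, glycolysis had 9 lower, nuclear export and pore 3 lower and the epithelial markers 4 lower, and the other lists kept their counts.

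A-to-I editing was compared to find which RNAs met the editor more often in the sorted particles. The editing score of a gene is its edited reads as a percentage of its reads. DCP1A, the most heavily edited of the fixed P-body genes, scored 19.5 ± 0.317% in sorted P-bodies and 6.18 ± 0.513% in cytosol (log2 odds ratio 1.88 ± 0.13, adjusted p = 5.3e-09, edgeR on edited and unedited reads). DDX6 scored 12.8 ± 0.981% against 5.52 ± 0.051% (adjusted p = 1.0e-08) and LSM14A 9.94 ± 0.108% against 3.69 ± 0.489% (adjusted p = 8.8e-09), while EDC4 scored 3.902 ± 0.814% against 3.07 ± 0.338% (adjusted p = 0.175). The largest rises were in genes listed with 0 edited reads in both cytosol libraries. BTF3, a subunit of the nascent-polypeptide-associated complex, had 237 of 4464 reads edited in sorted P-bodies and 0 of 12289 in cytosol, at least 217-fold higher over a floor of 3 edited reads per group. GPR50 was at least 94.6-fold higher, the spliceosomal LSM3 at least 68.5-fold, the protein disulfide isomerase PDIA6 at least 62.9-fold, PNP at least 50.5-fold, ANXA5 at least 49.2-fold, ERH at least 38.5-fold and GEMIN7 at least 34.8-fold. How edited sites were called is not given, and a filter on sites can produce a listed 0. These bounds assume that no filter did.

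The 8 largest A-to-I falls were in genes listed with 0 edited reads in both sorted libraries: GPLD1 (0 of 322 reads against 50 of 800, at least 6.71-fold lower), IGFBP5 (at least 4.51-fold), ADPRHL1 (4.46), NHEJ1 (4.39), GIPC3 (4.26), CACNG8 (3.34), IQSEC2 (2.97) and SLC35D3 (2.69). SLC35D3 did not pass with the replicate block (adjusted p = 0.089, edgeR). The bounds on these falls too assume that no filter on sites produced the listed 0. Of 11303 genes tested, 8311 were higher and 122 lower in sorted P-bodies (edgeR; 318 lower by limma and 71 with the replicate block), and the median log2 ratio was 1.37 with groups at 0 placed at their bound. The library medians were 7.19 and 7.41% in sorted P-bodies and 2.90 and 2.77% in cytosol, a ratio of group means of 2.58 (exact permutation test, two-sided p = 0.333, the smallest that these groups allow). With each library centred on its median, 3311 genes differed, 1940 higher and 1371 lower. Against that shift DCP1A stayed higher (0.48, adjusted p = 0.0038), EDC4 was lower (-0.999, adjusted p = 0.0057), and DDX6 (-0.07, adjusted p = 0.536) and LSM14A (0.13, adjusted p = 0.3004) did not differ by the edgeR test.

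By group, A-to-I scores rose in 22 of 24 P-body components (median 12.5% against 4.94%, camera adjusted p = 0.046), 30 of 31 secretory and endoplasmic reticulum genes (6.64% against 1.505%, adjusted p = 0.031) and 40 of 40 cell cycle and mitosis genes (8.28% against 2.79%, adjusted p = 0.031). They also rose in 56 of 60 chromatin modifiers (11.1% against 4.67%, camera adjusted p = 0.046) and 46 of 47 ubiquitin ligases and deubiquitinases (9.97% against 4.18%, adjusted p = 0.046). Replication-dependent histones lagged, with 5 of 14 higher (1.60% against 0.855%, camera adjusted p = 0.045, downwards). With each library centred on its median, the counts of higher and lower genes became 8 and 2 (P-body components), 19 and 4 (secretory and endoplasmic reticulum), 12 and 5 (cell cycle and mitosis), 10 and 11 (chromatin modifiers), 5 and 12 (ubiquitin ligases and deubiquitinases) and 1 and 4 (histones). Camera placed chromatin modifiers and ubiquitin ligases above all genes, although their median log2 ratios, with groups at 0 at their bound, lay 0.184 and 0.042 below. Adjusted over the list alone, 58 chromatin modifiers were higher and the other counts held. These 6 lists of 16 lost their call with an estimated correlation (adjusted p = 0.617) and with the replicate block (adjusted p from 0.068 to 0.138), and leaving out any 1 library ended the 5 upward calls. The histones' call was lost without sorted library 1 or 2 and held without either cytosol library.

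**Figure D3:**
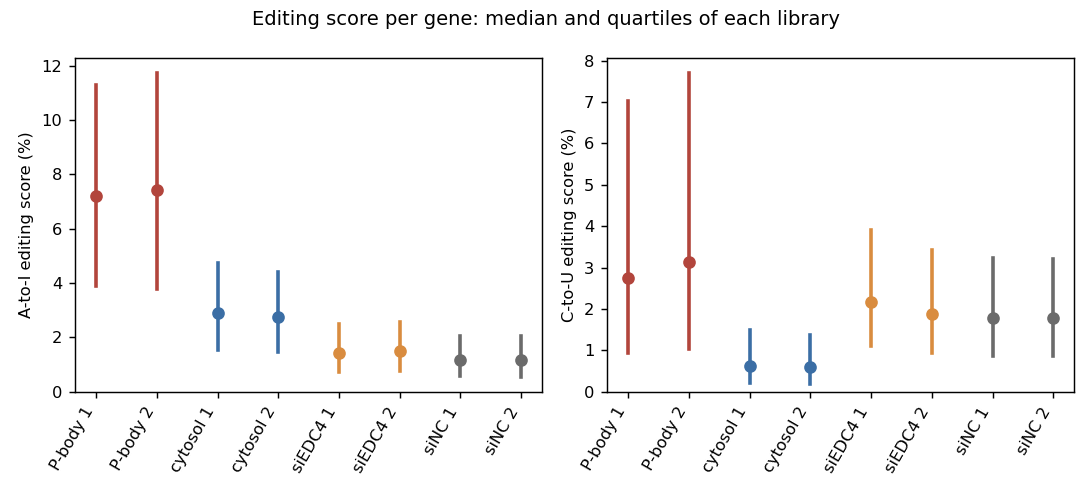
Median (point) and quartiles (line) of the editing score over genes in each library, for the A-to-I editor and the C-to-U editor. The A-to-I medians of the sorted P-body libraries, 7.19 and 7.41%, lie above those of the cytosol libraries, 2.90 and 2.77%, and the C-to-U medians, 2.76 and 3.13%, above 0.633 and 0.595%.

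The C-to-U editor gave a second reading of the same fractions. DDX6 scored 5.61 ± 1.09% in sorted P-bodies and 0.588 ± 0.188% in cytosol (adjusted p = 6.9e-06, edgeR), LSM14A 3.79 ± 0.379% against 0.231 ± 0.156% (adjusted p = 5.6e-06) and DCP1A 8.34 ± 0.181% against 1.40 ± 0.5004% (adjusted p = 9.4e-06). EDC4 had 7 of 2168 reads edited against 3 of 2770, a difference that did not pass (adjusted p = 0.164). The largest rises were again in genes listed at 0 edited reads in cytosol: the chaperonin HSPD1 (407 of 20263 reads against 0 of 25249, at least 169-fold higher), the lactate dehydrogenase LDHA (at least 155-fold), SF3B6 (113-fold), PPA1 (108-fold), BEX4 (103-fold), RPL7 (102.0-fold), EIF1B (94.4-fold) and OSTC (92.4-fold). As for A-to-I, these bounds assume that no filter on sites produced the listed 0.

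The largest C-to-U falls included MYH14 and GSN, which were among the 12 largest rises in abundance. PLEC, the cytolinker plectin, had 1 of 30843 reads edited in sorted P-bodies and 43 of 6019 in cytosol, a ratio of 220 with a 95% counting interval of 37.5 to 8903. MYH14 had 3 of 17562 against 27 of 2124 (ratio 74.4, 22.9 to 383) and CGN 0 of 12225 against 10 of 2047 (at least 19.9-fold lower). PEX5 was at least 5.82-fold lower, CMTR1 at least 2.98-fold and CAD at least 2.62-fold, and GSN had only 0 and 2 edited reads. The bounds on CGN, PEX5, CMTR1 and CAD rest on the same assumption about a listed 0. CAD did not pass by limma on log2 scores (adjusted p = 0.283), and GSN, CMTR1 and CAD did not pass without sorted library 1 or without sorted library 2 (adjusted p from 0.062 to 0.149, edgeR). By limma with the replicate block GSN and CMTR1 did not pass either (adjusted p = 0.090 and 0.087).

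Of 10613 genes tested for C-to-U editing, 7221 were higher and 31 lower in sorted P-bodies (edgeR; 274 lower by limma), with a median log2 ratio of 2.23 with groups at 0 placed at their bound. The library medians were 2.76 and 3.13% against 0.633 and 0.595%, a ratio of group means of 4.79 (exact permutation test, two-sided p = 0.333, the smallest allowed). Centring each library on its median left 958 higher and 652 lower, among which DDX6 (0.86, adjusted p = 0.045) and LSM14A (1.64, adjusted p = 0.013) stayed higher and DCP1A did not pass (0.22, adjusted p = 0.606, edgeR). By group, C-to-U scores rose in 21 of 22 P-body components (median 4.93% against 0.479%), 21 of 24 translation factors (4.04% against 0.1101%), 24 of 25 secretory and endoplasmic reticulum genes (5.44% against 0.120%) and 36 of 37 cell cycle and mitosis genes (2.98% against 0.152%), each with a camera adjusted p of 0.040. The counts were the same adjusted over the list alone. With centring they became 5 higher and 2 lower, 15 and 0, 13 and 0, and 9 and 1, in the same order. The 4 lists of 14 lost their call with an estimated correlation (adjusted p = 0.775) and with the replicate block (adjusted p = 0.073), and all but cell cycle and mitosis lost it without sorted library 2. All 4 lost it without sorted library 1, cytosol library 1 or cytosol library 2, and without either cytosol library cytosolic ribosomal proteins passed instead, downwards (median log2 odds ratio with every library 2.16, against 2.33 for all genes).

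The knockdown asked how loss of EDC4, which helps hold P-bodies together, changes the RNA. EDC4 itself (ENSG00000038358.15, chromosome 16, 67873052 to 67884499 in hg38) had 245 and 186 reads in the siEDC4 libraries and 684 and 609 in the siNC libraries, and its level was 33.9% of siNC (log2 fold change -1.56 ± 0.14, adjusted p = 2.6e-25, and 1.4e-05 with the siNC libraries as 2 samples, edgeR). TPM4, a tropomyosin that stabilises actin filaments, rose from 106 to 202 ± 5.27 RPM, CPM of the reads column (log2 fold change 0.94 ± 0.12, adjusted p = 1.5e-11, edgeR). Larger folds came from genes with few reads: ARHGDIG (1.41 ± 0.26), the interleukin receptor IL23R (1.35 ± 0.24) and CCDC80 (1.05 ± 0.24), at 6.02 to 8.45 RPM in siNC. LPL (0.86), TFPI (0.85), BMP6 (0.83) and SELENOP (0.81) also rose, and SAMD11 (-0.66), STMN3 (-0.60), PIDD1 (-0.60), TM7SF3 (-0.59), CCDC86 (-0.59), NOL9 (-0.49) and KIF18B (-0.47) fell. ADARB1 was at 544 ± 27.6 against 412 RPM (0.40 ± 0.11, adjusted p = 0.046), LSM14A at 739 ± 20.1 against 590 RPM (0.33 ± 0.11, adjusted p = 0.187), DDX6 at 1465 ± 14.6 against 1335 RPM (adjusted p = 0.891) and DCP1A at 128 ± 14.4 against 154 RPM (adjusted p = 0.522, all edgeR).

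**Figure D4:**
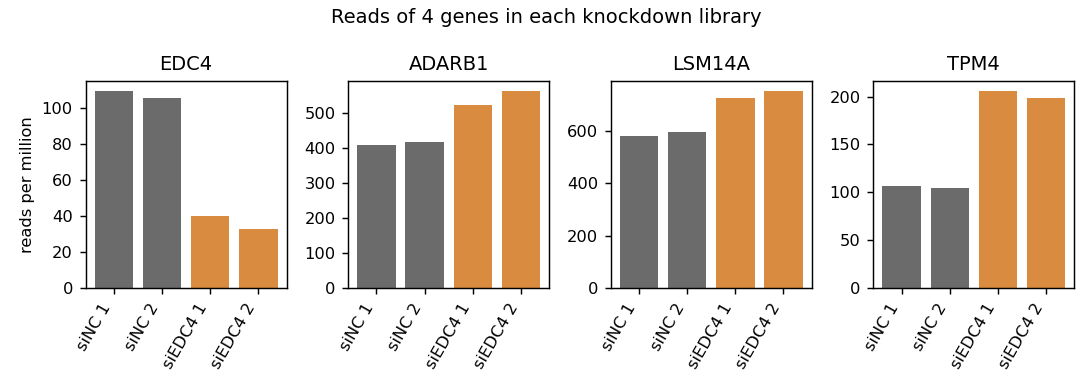
RPM for EDC4, ADARB1, LSM14A and TPM4 in each siNC library (grey) and siEDC4 library (orange); bars start at 0. EDC4 stood at 110 and 106 in siNC and at 40.4 and 32.7 in siEDC4.

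Of 10642 genes with reads in the A-to-I knockdown table, 46 were higher and 14 lower (edgeR). DESeq2 called 3, EDC4, TPM4 and GANAB (0.61, adjusted p = 0.0092), the last named after its values were seen. With the siNC libraries as 2 samples 154 genes passed, LSM14A (adjusted p = 0.0099) among them. With the replicate block as well 303 were higher and 218 lower, LSM14A (adjusted p = 4.7e-05) and DCP1A (adjusted p = 0.016) among them (edgeR). Without siNC library 1 the count was 32, and CCDC80, TFPI, BMP6, STMN3, NOL9, KIF18B and ADARB1 did not pass. LPL, TFPI, STMN3 and NOL9 did not pass without siNC library 2. With the siNC libraries as 2 samples LPL, TM7SF3 and CCDC86 did not pass (adjusted p = 0.053, 0.114 and 0.193, edgeR), nor did STMN3, NOL9 and KIF18B under library-size scaling (adjusted p = 0.055, 0.061 and 0.055). In gene groups, ribosomal proteins had a median log2 change of -0.10 (0 of 77 passed, camera adjusted p = 4.0e-05), cell cycle and mitosis genes -0.13 (0 of 40, 5 lower adjusted over the list alone, camera adjusted p = 0.00019) and replication-dependent histones 0.38 (0 of 9, 2 higher adjusted over the list alone, camera adjusted p = 0.0021). All 3 lost the call with an estimated correlation (adjusted p = 0.987), and chromatin modifiers, at -0.07, had a camera adjusted p of 0.060, and of 0.039 with the replicate block and the siNC libraries as 2 samples together.

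After the knockdown no single gene's editing score passed the test, and in simulated data of this layout no 4-fold change passed either. LSM14A scored 4.42 ± 0.405% for A-to-I in siEDC4 and 3.02% in siNC, DCP1A 4.24 ± 1.88% and 3.14%, DDX6 2.42 ± 0.513% and 2.17%, and EDC4 1.15 ± 0.106% and 0.928%, with adjusted p from 0.845 to 0.957 (edgeR). For C-to-U, LSM14A scored 4.71 ± 0.906% and 4.34%, DCP1A 3.83 ± 1.48% and 3.54%, DDX6 1.41 ± 0.525% and 1.35%, and EDC4 had 1 of 431 reads edited against 5 of 1295. The genes with the highest A-to-I scores in siNC were IFITM2 (28.7% against 28.4 ± 1.25% in siEDC4), ATP5MPL (20.3% against 22.1 ± 1.65%), MRPS9 (16.2% against 17.9 ± 0.322%), C2orf76 (16% against 18.2%), MED18 (14.5% against 14.7 ± 1.65%), ID3 (14.1% against 6.93 ± 9.80%), CCDC12 (13.9% against 16.7 ± 5.05%) and SNRPD3 (13.7% against 13.96 ± 0.109%). Among those with the highest C-to-U scores were TSPAN7 (21.7% against 15.7 ± 0.609%), CTU2 (18.9% against 16.6 ± 1.88%), TMSB15A (17.7% against 17.5 ± 2.97%), NDUFB5 (17.7% against 17.5 ± 3.16%), PCLAF (17.01% against 12.2 ± 2.72%), ENDOG (16.2% against 19.5 ± 1.16%) and SLC25A10 (14.95% against 13.1 ± 1.82%), and none of these genes passed by edgeR.

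The median A-to-I score was 1.43 and 1.5% in siEDC4 and 1.179 and 1.16% in siNC (ratio 1.25, exact permutation test, two-sided p = 0.333, the smallest allowed). The median C-to-U score was 2.17 and 1.89% against 1.78 and 1.78% (ratio 1.14, exact permutation p = 0.667). By edgeR 0 of 9157 genes passed for A-to-I, with an unadjusted p under 0.05 in 458 higher and 33 lower genes, and 0 of 9646 for C-to-U, with 330 and 47. By limma the counts were also 0, with 342 and 260 at an unadjusted p under 0.05. With siNC as 1 sample, genes without an edited read in siEDC4 could not enter, while genes without any in siNC could (218 for A-to-I, 129 for C-to-U). The filter thus tilts the split of higher and lower genes upwards. With the siNC libraries as 2 samples both kinds could enter, and 0 of 9271 (A-to-I) and 0 of 9745 (C-to-U) passed by edgeR. With the replicate block and the siNC libraries as 2 samples, 25 genes were higher and DIPK1B lower for A-to-I, and for C-to-U B4GALNT3, PPP4C and RPS18 were higher and FYN lower. These 5 genes were named after their values were seen. Of the lists, cytosolic ribosomal proteins alone passed for A-to-I (3.88% against 2.77%, 0 of 70 genes and 3 adjusted over the list alone, camera adjusted p = 0.036), and lost the call with an estimated correlation (adjusted p = 0.876), with the replicate block and the siNC libraries as 2 samples together (adjusted p = 0.068) and without either siNC library, but not with the siNC libraries as 2 samples alone (adjusted p = 0.0066). For C-to-U 0 lists passed by camera, and zinc finger genes did with the replicate block and the siNC libraries as 2 samples together (downwards, adjusted p = 0.035, against 0.241 in the fit with siNC as 1 sample). With the siNC libraries as 2 samples alone the smallest list p was an adjusted p = 0.066 (camera). In data simulated with this layout, 0 of 58 genes changed 4-fold passed for A-to-I and 0 of 62 for C-to-U, against 11 of 64 and 17 of 61 with the siNC libraries as 2 samples.

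Genes more edited in the cytosol were also more abundant in sorted P-bodies. Across 11969 genes the P-body log2 fold change had a Spearman correlation of 0.372 with the cytosol A-to-I score (0.311 given gene length). Across 11776 genes it had 0.566 with the cytosol C-to-U score (0.529 given gene length). With the siNC scores, from other libraries, the values were 0.251 over 10640 genes and 0.221 over 10826. The change in score between sorted P-bodies and cytosol had a Spearman correlation with that after the knockdown of 0.012 over 9104 genes for A-to-I and 0.064 over 9144 for C-to-U. Those values used log2 ratios. By library, on differences of the score in percentage points, they were 0.123 and 0.104 for A-to-I and 0.225 and 0.038 for C-to-U. There, sorted and cytosol libraries were paired by number, and each siEDC4 library was set against the summed siNC reads. Genes are not independent replicates, so these 6 relations across genes carry no p-value.

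**Figure D5:**
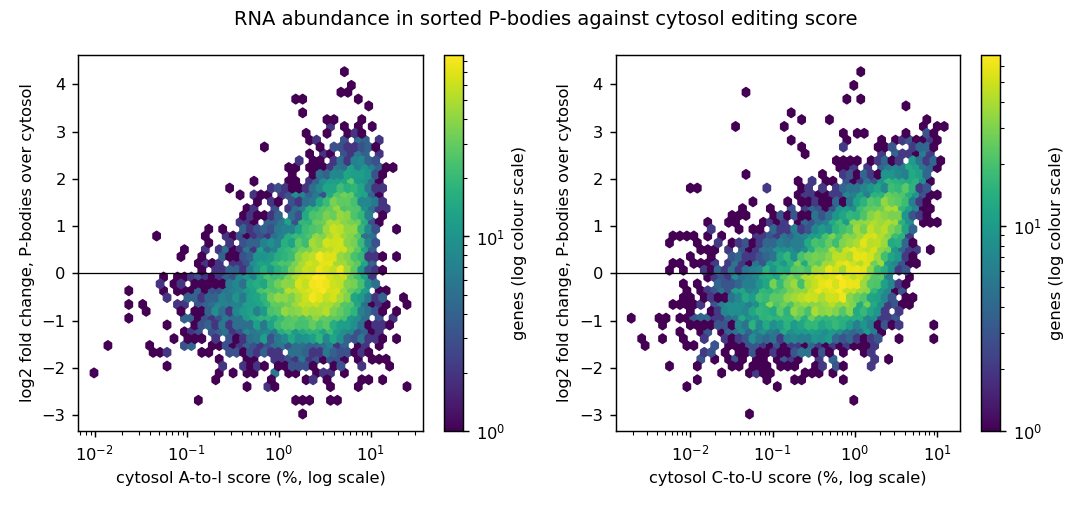
Log2 fold change of RNA abundance, sorted P-bodies over cytosol, against the mean cytosol editing score (log scale) for 11166 genes (A-to-I, left) and 10072 genes (C-to-U, right) with a score above 0; colour gives the number of genes per hexagon (log scale). Over all genes the Spearman correlations are 0.372 and 0.566.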

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

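limma on log2 scores, planned as the test of the editing tables, became an alternative once edited reads were found in the files. The planned fit with the siNC libraries as 2 samples likewise became an alternative. Chosen after the data were seen were most alternatives for list tests, the replicate block with the siNC libraries as 2 samples, all settings of the knockdown reads and the limit of 500 reads; the remaining settings were planned. The total counts of genes past the threshold in the sort stayed within 1.5 times under every other scaling, filter, pseudocount, tool, block and left-out library: 8077 to 12715 for abundance, 7460 to 7990 (A-to-I) and 5383 to 7068 (C-to-U) without 1 library. The small counts of genes with a lower score moved more: 122 for A-to-I became 318 by limma, 71 with the block and 41 to 99 without 1 library, and 31 for C-to-U became 274 by limma, 27 with the block and 12 to 21 without 1 library. Centring each library on its median reduced the A-to-I count to 3311 and the C-to-U count to 1610, since the shift of the whole library is then removed. The replicate block gave 11142, 8224 and 7158 genes in the sort, and in the knockdown, with the siNC libraries as 2 samples, 26 (A-to-I), 4 (C-to-U) and 521 (reads) against 0, 0 and 60. In the sort 10708 of the 10841 abundance calls held with the block; of the named items it changed those given beside their results. The knockdown's reads gave 154 genes with the siNC libraries as 2 samples, 3 by DESeq2 and 32 to 51 without 1 siNC library, and 0 in both editing tables without either. Leaving out a siEDC4 library left 1 sample against 1 with siNC as 1 sample, with no spread to test against. It was not run, nor was 1 siEDC4 library against the siNC libraries as 2 samples. Of the list tests, 0 passed with an estimated correlation in any table where some had passed; 8 to 9 passed without 1 library for abundance, 0 to 1 for the sort's A-to-I and C-to-U scores and 0 for the knockdown's A-to-I scores. With the block 0 passed in the sort's editing tables and the knockdown's A-to-I table and 1 in its C-to-U table. The estimated correlation has little power with so few libraries, so list calls lost with it decide nothing.

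Given gene length, the correlations of P-body log2 fold change were 0.311 and 0.529 with the cytosol scores and 0.213 and 0.204 with the siNC scores; over genes with a mean of 50 counts the last was 0.220, and over genes with 500 reads the relation of sort and knockdown changes in A-to-I was 0.047. Signs turned mostly with centring: in the sort for EDC4 (-0.999 A-to-I, -0.83 C-to-U) and DDX6 (-0.072, A-to-I); in the knockdown's A-to-I scores for ATP5MPL (-0.15), C2orf76 (-0.082), MRPS9 (-0.13), MED18 (-0.27), CCDC12 (-0.0047), SNRPD3 (-0.26) and DDX6 (-0.15). In the knockdown's C-to-U scores they turned for TMSB15A (-0.21), DDX6 (-0.17), LSM14A (-0.091) and DCP1A (-0.10). None of these knockdown values passed in any setting. With the replicate block IFITM2 stood at 0.017 (limma 0.019) and TMSB15A at -0.011 (limma -0.027), and limma alone gave TMSB15A -0.030 (-0.031 and -0.024 with pseudocounts 10 times smaller and larger). Without 1 siNC library the A-to-I values ran from -0.28 to 0.30 for IFITM2, -0.12 to 0.58 for C2orf76, -0.28 to 0.37 for SNRPD3 and -0.27 to 0.50 for MED18. The C-to-U values ran from -0.28 to 0.27 for NDUFB5, -0.054 to 0.075 for TMSB15A, -0.0095 to 0.72 for ENDOG, -0.46 to 0.0012 for SLC25A10 and -0.23 to 0.39 for DDX6. The causes were not tested. Most named falls in the sort rest on fewer than 60 edited reads in the cytosol.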

Other observations

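All tests below were chosen after the results were seen, and for the C-to-U matching test, the single factor per library and the editor dose the prediction was also written after the value was seen.

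Enriched mRNAs were AU-rich and long. The 4466 coding genes higher in sorted P-bodies had a median of 43.1% G or C at codon position 3, against 68.8% for the 4530 lower genes, and across 13575 genes the Spearman correlation with the log2 fold change was -0.53 (-0.49 given gene length). Over 5 bins of 2715 genes from the lowest to the highest GC content at codon position 3, the median log2 fold change ran 0.89, 0.30, -0.20, -0.39 and -0.42, and 2010 genes of the lowest bin but 247 of the highest were higher. 3' UTR length (0.27, and 0.15 given gene length) and coding length (0.37, and 0.23) went the other way, with median 3' UTRs of 1644 bases in higher and 726 in lower genes. The gain in editing score followed GC content too, at -0.34 for both editors, but ran against coding length (-0.23 for both), unlike the change in abundance. A library bias on GC content was not tested.

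A list of actin and spectrin cytoskeleton genes was made after such genes were seen among the largest rises, and it holds those genes, so it is no independent evidence of a direction. Of its 99 measured genes 53 were higher and 27 lower (median 0.48), among them SYNE2, UTRN, MYH10, IQGAP1 (3.33) and SPTBN1 (3.15). Of 44 microtubule motors and associated proteins, 18 were higher and 10 lower (median 0.09), and the lists were not tested against each other.

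Actin and spectrin mRNAs leading the sorted fraction was weighed against transcript length and against cytoskeleton-bound RNA carried along in the sort. The list's median lay at the 76.2 percentile of 10000 random lists matched on length and expression (matched median 0.39), so length may account for the shift of the list as a whole. Their editing lagged: the median log2 score ratio was 0.82 for A-to-I and 1.44 for C-to-U, against 1.33 and 2.35 in lists matched on abundance change and expression, at a percentile of 0 for both. Those lists were not matched on length or GC content. Across genes the gain in score fell with coding length (-0.23 for both editors) and with GC content at codon position 3 (-0.34 for both). The test therefore cannot separate the lag from length or GC content. SYNE2 scored 4.42 ± 0.124% for A-to-I in sorted P-bodies and 4.98 ± 0.293% in cytosol, MYH9 4.15 ± 0.146% and 5.63 ± 0.289%, and UTRN 0.269 ± 0.0084% and 0.915 ± 0.194% for C-to-U, while DBN1 went the other way (2.74 ± 0.052% and 1.60 ± 0.167% for A-to-I), and the list's median score was higher in sorted P-bodies for both editors. A candidate explanation, as a hypothesis, is that part of this RNA joined the sorted material without much contact with the editors, and mRNAs held in P-bodies in a form the editors seldom reach stays open, untested.

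Editing scores of most genes being higher in sorted particles was weighed against depth and a single factor per library. The sorted libraries held fewer A-to-I reads of listed genes (14310317 and 12224360) than the cytosol libraries (15237703 and 15947999). Among 7582 genes with fewer reads in both sorted than in both cytosol libraries, most of those tested, the median log2 A-to-I ratio was still 1.31. Both argue against greater depth in the sorted libraries. After centring, 29.3% of 11303 genes still differed, which argues against 1 factor shared by all genes of a library as the whole cause. Contact with the editors inside P-bodies stays open beside differences in library input, which went with the fraction.

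The higher median A-to-I score after EDC4 knockdown was weighed against editor dose and against RNA leaving P-bodies. ADARB1 reads were higher by 0.40 on the log2 scale and the median gene's A-to-I score by 0.29, so a higher dose of an editor that shares the ADARB1 sequence could account for the shift; whether the editor does is not given in the sources used here, and dose cannot be told apart from knockdown in these libraries. The knockdown's A-to-I change had a Spearman correlation of 0.0077 with P-body enrichment across 9156 genes, where release of RNA from P-bodies predicted a value below -0.1. The changes of single genes were imprecise: in simulated data of this layout 0 of 58 genes changed 4-fold passed. Such noise weakens any correlation, so this value cannot decide for or against release.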
